A study of Arabidopsis thaliana with 12 samples.

How the data were processed

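The deposited files are Agilent Feature Extraction text files of 12 one-colour (Cy3) 4x44k Arabidopsis arrays, made with version 10.7.1.1 and protocol GE1_107_Sep09, and a series value table. Per the file headers and the labels, the authors measured Cy3 intensity; the processed signal is a background-corrected intensity on a linear scale, and the deposited value table holds the median signal intensity per spot in 11 of its 12 columns. The labels state growth on MS plates at 23 and 18 °C with 16 h of light, RNA from at least 30 seedlings per plate with an integrity number of at least 7.5, 150 ng of RNA per labelling and 2 biological replicates per combination. The hour of sampling, whether replicates came from separate plates, and whether more than 1 transgenic line was used are not given in the sources used here. The genome build behind the probe annotation does not match the reference held, so no coordinates are printed.

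Each array has 45220 features, of which 1417 are controls, and 43603 distinct probes among the others. Through the locus code each probe carries, 34285 probes matched the reference table of symbols and 9318 did not; the matched probes cover 25383 loci. Probes were kept if well above background, by the scanner's own call, on both arrays of at least 1 of the 6 groups: 33228 passed, 28841 of them with a locus. Saturated spots numbered 0, and 17 probes were left out for outlier calls of the scanner. A gene was represented by its kept probe with the highest mean over the 12 arrays, which gave 20806 genes; 6200 had more than 1 kept probe, and for some of these the report gives the range.

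The processed signal was taken to log2 and each array's 75th percentile was subtracted; that percentile lay between 2700 and 5646 and the median between 522 and 1082. The SD between replicate arrays was 0.145 to 0.182. In limma 3.58.1 all 12 arrays were fitted with 6 group means, contrasts were formed and variances moderated by empirical Bayes, with 6 residual and 2.08 prior degrees of freedom, 8.08 in total. P-values were adjusted over the genes of a contrast by Benjamini-Hochberg, and a gene passed at adjusted p below 0.05. The 11 contrasts are each cold time against 0 h in each genotype, 48 h against 3 h in wild type, overexpression against wild type at each time and averaged over the times, and the difference of the genotypes' responses at 3 h and at 48 h.

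Before the data were examined, 27 gene lists with 400 entries were written from general knowledge, covering cold signalling, hormones, metabolism, chromatin, growth and tissue markers; 389 entries were tested, 5 to 27 per list. Members not tested were DDF2, PAP2, HSP17.6A, HSP21, HSP22, TSF, SAG12, WUS and CLV3, dim on all groups, and DHAR1 and ACT2, absent from the array. Lists were tested with camera at a preset correlation of 0.01, adjusted over lists within a contrast, and again with the correlation estimated from the residuals and with fry. Camera called 87 of 297 list tests, 12 with an estimated correlation, and fry called 159.

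Named genes follow a rule fixed beforehand: RDM4, the cold genes CBF1, CBF2, CBF3, COR15A, COR47, RD29A and KIN1, per comparison the 10 largest rises and 10 largest falls (5 and 5 for the overexpression cold comparisons, 48 h against 3 h, the average and the differences) among genes with a symbol whose arrays do not overlap between groups, and up to 4 passing members per list described. Genes outside this rule, such as those of the low oxygen list, were chosen after values were seen.

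Alternatives tried were normexp background correction, quantile and median scaling, no background filter, probes above background on all arrays, the deposited value table, the mean of a gene's probes, only the compared arrays, blocks for replicate number, scan day and slide, trended and robust variances, array weights, a 2-fold minimum and leaving out each array in turn. The planned normexp input, the mean signal, is not in the files, so the median signal and median background were used with an offset of 50. Chosen after results were seen were the scanner median signal, slide as a random block, and list tests under normexp, the value table, scan day, slide and single array omission. The 12 arrays lie on 5 slides scanned on 2 days: the only slide with both genotypes holds the wild type replicate 2 arrays and overexpression 48 h replicate 1. Slide as a fixed block leaves 2 residual degrees of freedom, as does fitting only the arrays compared, and scan day or replicate blocks leave 5.

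In a check of the tests, 200 genes were changed by a known fold in data simulated with the means and fitted variances of these arrays, 5 times. Noise was drawn independently for each gene and array, with no slide or scan day effect and no correlation between genes. Between genotypes at 0 h 56.4 % of genes changed 1.25-fold were recovered, 87.2 % at 1.5-fold, 92.8 % at 2-fold and 98.4 % at 4-fold, with 4.45 % false calls. For wild type at 3 h these were 54, 88.4, 94 and 97.2 %, with 5.01 % false, for the average over times 88, 96.4, 97.2 and 99.2 %, with 4.51 % false, and for the difference of responses at 3 h 23.6, 73.6, 92.8 and 94 %, with 3.4 % false. A list shifted 1.25-fold was called in 5 of 5 simulations. These rates do not cover a slide effect, which nearly coincides with genotype here, or lists whose genes move together. R 4.3.3 was used with the packages data.table (1.17.8) and jsonlite (2.0.0), and Python 3.11.15 with matplotlib 3.10.9.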

Results

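RNA from leaves of 2-week-old Arabidopsis thaliana seedlings, Col wild type and 35S::RDM4 overexpression plants, was measured on 12 one-colour arrays before cold (0 h, room temperature) and after 3 h and 48 h at 4 °C. Each of the 6 combinations of genotype and time has 2 arrays, which the labels call biological replicates (n = 2). Adjusted p-values come from limma and describe only the spread between these samples. After filtering, 20806 genes were tested; 73.1 to 76.5 % of probes were well above background on each array, and replicate arrays correlated at r = 0.9956 to 0.997 across genes, which are not independent replicates.

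RDM4 (AT2G30280), an IWR1-type factor that works with RNA polymerase II and polymerase V, was higher in the overexpression plants in every array at all 3 times. The difference was 44.1-fold at 0 h (log2 5.46 ± 0.10, standard error, n = 2, adjusted p = 1.76e-07), 52.0-fold at 3 h (log2 5.70, adjusted p = 1.25e-07) and 44.0-fold at 48 h (log2 5.46, adjusted p = 1.76e-07). In wild type the endogenous transcript fell in the cold by 0.40 on the log2 scale at 3 h (1.32-fold, adjusted p = 0.00602) and by 0.43 at 48 h (adjusted p = 0.00334). In the overexpression plants, where the probe reads transgene and endogenous RNA together, the signal did not pass at 3 h (log2 −0.16, adjusted p = 0.167, but −0.19 and 0.0412 with slide as a block) and fell by 0.43 at 48 h (adjusted p = 0.00325). Before scaling it was 199672 to 293236 there. At 48 h COR47, RD29A and KIN1 had signals of this size that hardly followed the array's scale. The size of the fall and of the genotype differences is limited by this. Under quantile scaling the RDM4 difference of responses passed, at 0.42 at 3 h (adjusted p = 0.00416) and 0.29 at 48 h (0.0177). Group means on the log2 scale relative to each array's 75th percentile were 0.54 ± 0.06 (SD), 0.15 ± 0.02 and 0.12 ± 0.02 in wild type and 6.01 ± 0.14, 5.84 ± 0.10 and 5.58 ± 0.19 in the overexpression plants. Within scan days the difference was 5.52 and 5.4 at 0 h, 5.75 and 5.65 at 3 h and 5.44 at 48 h, and within the only slide holding both genotypes it was 5.57 at 48 h.

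**Figure D1:**
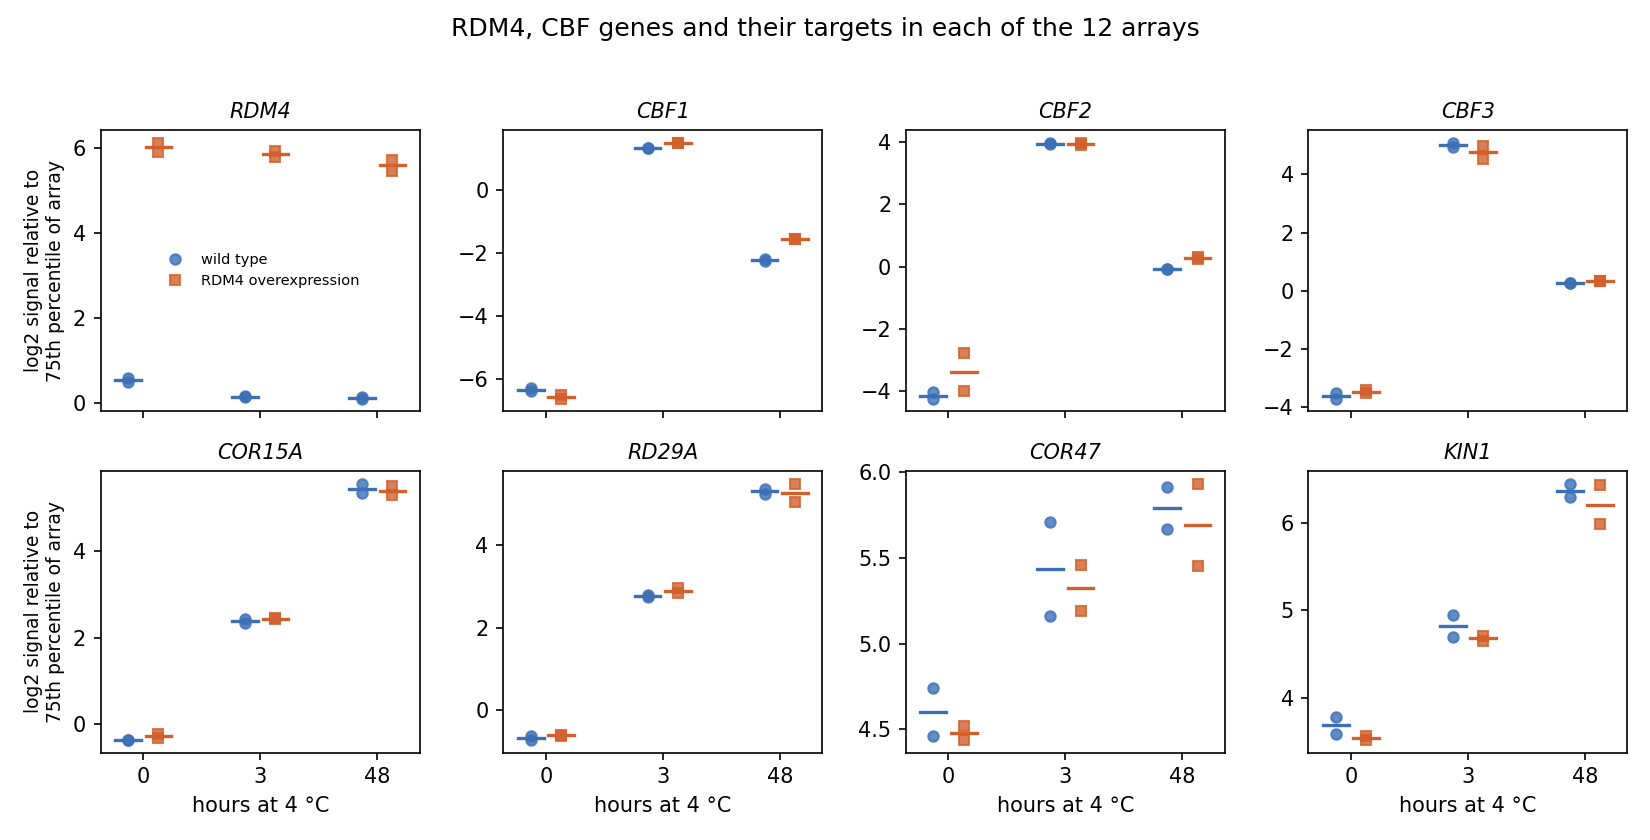
Signal of RDM4, CBF1, CBF2, CBF3, COR15A, RD29A, COR47 and KIN1 (vertical axis, log2 relative to the array's 75th percentile) at 0, 3 and 48 h of cold. Points are single arrays, n = 2 per genotype and time, and short horizontal lines mark group means. RDM4 separates the genotypes at all times, log2 5.46 to 5.70, while the values of the other 7 genes lie close together between genotypes.

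The comparison of 3 h with 0 h in wild type asks which transcripts change in the first 3 h of chilling. No room temperature array was made at 3 h or 48 h, and the hour of sampling is not stated. Changes by time of day are therefore counted together with those of chilling in all cold comparisons. The largest rises among genes with a symbol were those of the CBF (DREB1) transcription factors, which bind the C-repeat promoter element of cold-regulated genes. CBF3 (AT4G25480) rose 393-fold (log2 8.62 ± 0.14, n = 2, adjusted p = 1.06e-09), CBF2 (AT4G25470) 270-fold (log2 8.07 ± 0.31, adjusted p = 1.08e-07) and CBF1 (AT4G25490) 202-fold (log2 7.66 ± 0.05, adjusted p = 4.61e-11). Their targets followed more weakly: RD29A 10.8-fold (log2 3.43 ± 0.12, adjusted p = 7.23e-08), COR15A 6.79-fold (log2 2.76 ± 0.08, adjusted p = 3.16e-08) and KIN1 2.18-fold (log2 1.13 ± 0.14, adjusted p = 1.56e-04). The CBF1 signal before scaling was only 32 and 69 in wild type at 0 h, on arrays with medians of 522 and 1036. In the overexpression plants at 0 h it was 44 and 50. Fold rises of CBF1 therefore rest on a low baseline, although called above background. Of 20806 genes, 14164 (68.1 %) passed, 6409 higher and 7755 lower; at least 2-fold changed 1302 higher and 657 lower.

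Genes of several other functions rose with them in wild type at 3 h. The abscisic acid hydroxylase gene CYP707A3 rose 39.4-fold (log2 5.30 ± 0.04, its probes ranged from 5.30 to 6.97), the B-box factor genes BBX29 34.3-fold (log2 5.10 ± 0.08) and BBX31 30.2-fold (log2 4.92 ± 0.05), and the MYB-like RVE2 31.5-fold (log2 4.98 ± 0.04). The terpene synthase gene TPS03 rose by log2 5.90 ± 1.22 (adjusted p = 0.00261), with probes from 3.10 to 5.90 and 3.41 under normexp background correction. RRTF1 rose at least 16.3-fold and DDF1, another DREB1 member, at least 7.93-fold. Such bounds are given where a group was not well above background: on each array its value was set to the higher of the gene's own value and the lowest normalised signal of any probe well above background. The largest falls were those of PCR1 27.0-fold (log2 −4.76 ± 0.05), XTH25 19.4-fold (log2 −4.28 ± 0.08), SEN1 16.6-fold (log2 −4.06 ± 0.07), the branched-chain aminotransferase gene BCAT-2 16.6-fold (log2 −4.05 ± 0.04), the inositol oxygenase gene MIOX2 12-fold (log2 −3.58 ± 0.07) and PCC1 11.5-fold (log2 −3.53 ± 0.12). MIOX4 fell at least 16.6-fold, the signalling peptide gene CLE18 at least 8.16-fold, PUM20 at least 5.20-fold and the MADS-box gene GOA at least 3.00-fold.

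Of the 27 gene lists, 9 were called at 3 h in wild type by camera. It compares the mean test statistic of the members with that of all other genes, at a preset correlation of 0.01. With an estimated correlation 2 stayed called. All 15 early cold transcription factors were higher (15 adjusted over the list alone, median 2.05, adjusted p = 3.19e-10, and adjusted p = 0.0103 with an estimated correlation). Among them were ZAT10 (log2 3.65 ± 0.05), ERF6 (3.00), RAV1 (2.46) and HSFC1 (2.46). Of 20 flavonoid and anthocyanin genes 19 were higher (19 adjusted over the list alone, median 2.50, adjusted p = 2.56e-12, and adjusted p = 0.0133 with an estimated correlation). They were led by LDOX (3.49), FLS1 (3.42), the activator PAP1 (3.31) and MYB11 (at least 2.48-fold). The 5 DREB1 family members were all higher (median 7.66, adjusted p = 1.63e-04, and adjusted p = 0.11 with an estimated correlation). Of 18 members of the CBF regulon 16 were higher and 2 lower (16 and 2 adjusted over the list alone, median 1.35, adjusted p = 7.1e-06, and adjusted p = 0.3 with an estimated correlation). GOLS3 (4.38 ± 0.04), BAM3 (3.77) and COR15B (3.38) rose, and the chloroplast membrane protein genes COR413IM1 (−0.96) and COR413IM2 (−0.31) fell.

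Hormone and clock genes moved in wild type at 3 h as well. Of 16 abscisic acid genes 15 were higher and 1 did not pass (15 adjusted over the list alone, median 0.96, adjusted p = 4.56e-08, and adjusted p = 0.094 with an estimated correlation). Among them were CYP707A1 (2.49), the phosphatase gene HAI2 (2.49, 1.43 under normexp) and the synthesis gene NCED3 (2.11). Of 22 jasmonate genes 15 were higher and 3 lower (15 and 3 adjusted over the list alone, median 0.77, adjusted p = 1.63e-04, and adjusted p = 0.094 with an estimated correlation). Among them were LOX4 (2.99), JAZ7 (2.39) and JAZ1 (2.26). Of 20 clock genes 15 were higher and 2 lower (15 and 2 adjusted over the list alone, median 1.38, adjusted p = 8.92e-06, and adjusted p = 0.094 with an estimated correlation). Among them were RVE1 (3.70), PRR5 (3.52), CCA1 (3.11) and ELF4 (2.85); the hour of sampling is not stated. Compatible solute and starch genes split 10 higher, 6 lower and 2 not passing (10 and 6 adjusted over the list alone, median 0.45, adjusted p = 0.0236, and adjusted p = 0.455 with an estimated correlation), with SPS4F (2.68) and GOLS2 (2.43) among the rises. Of 14 ribosome biogenesis genes 10 were higher and 1 lower (10 and 1 adjusted over the list alone, median 0.32, adjusted p = 0.0236, and adjusted p = 0.3 with an estimated correlation). Among them were FIB2 (0.62) and NOP56 (0.57).

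The remaining lists were not called at 3 h in wild type. Of 21 salicylate and defence genes 5 were higher, 12 lower and 4 did not pass (5 and 12 adjusted over the list alone, median −0.47, adjusted p = 0.212), with PR1 (−2.86 ± 0.13), PR2 (−2.74 ± 0.05), NIMIN1 (−1.37) and CYP71A13 (−1.42, −0.89 in the deposited value table) lower. Of 27 RNA-directed DNA methylation genes 4 were higher and 14 lower (4 and 14 adjusted over the list alone, median −0.15, adjusted p = 0.226). Among them were DME (−0.80), DRM2 (−0.68) and AGO6 (0.60). Heat shock genes had a median of −0.18 and a mean of 0.03, with DREB2A (2.22) higher and HSFA7A (−2.06), HSP15.7 (−1.21) and MBF1C (−1.13) lower. COR47 rose 1.79-fold (log2 0.84 ± 0.22, adjusted p = 0.00878, probes 0.84 to 1.3) but did not pass without wild type 0 h replicate 2 (0.70, adjusted p = 0.0618) or wild type 3 h replicate 1 (0.56, adjusted p = 0.0625). Normexp ended the calls of DDF1 and GOA, and it brought RRTF1 (log2 1.83 against 5.55), CLE18 (−2.45 against −4.68), PUM20 (−2.52 against −4.66) and MIOX4 (−2.55 against −4.45) nearer 0. All of these were near background in a group.

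After 48 h the question is which responses last and which are late, and here the cold-regulated effector genes were highest in wild type. GOLS3, which makes galactinol for raffinose synthesis, rose 262-fold (log2 8.03 ± 0.04, n = 2, adjusted p = 9.32e-12), RD29A 62.1-fold (log2 5.96 ± 0.12, adjusted p = 2.32e-09) and COR15A 56.7-fold (log2 5.82 ± 0.08, adjusted p = 5.44e-10). COR27 rose 51.6-fold (log2 5.69 ± 0.06), COR15B 38.3-fold (log2 5.26 ± 0.17), KIN1 6.38-fold (log2 2.67 ± 0.14) and COR47 2.29-fold (log2 1.19 ± 0.22, probes 1.19 to 2.46). The CBF transcripts were still above 0 h, CBF1 17.3-fold (log2 4.11 ± 0.05, 2.48 under normexp), CBF2 16.7-fold (log2 4.06 ± 0.31) and CBF3 14.6-fold (log2 3.87 ± 0.14). In all, 16382 genes (78.7 %) passed, 8256 higher and 8126 lower, with 1910 and 1916 changed at least 2-fold.

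RVE2 stayed 25.3-fold higher in wild type at 48 h (log2 4.66) and the defensin gene PDF2.1 rose 24.5-fold (log2 4.62). ARI12 rose at least 31.7-fold, the vernalisation gene VIN3 at least 11.6-fold and the nitrate transporter gene NRT2.4 at least 5.56-fold, although normexp ended the NRT2.4 call and moved ARI12 from log2 5.79 to 2.61 and VIN3 from 5.55 to 1.68. The falls were led by PAP14 (at least 58.4-fold) and the seed storage gene PAP85 (at least 19.4-fold), MIOX4 (at least 17.3-fold), the small peptide gene RTFL21 54.2-fold (log2 −5.76 ± 0.07) and the amylase gene BAM5 45.9-fold (log2 −5.52 ± 0.09). AACT1 fell 43.6-fold (log2 −5.45 ± 0.22), the threonine aldolase gene THA1 39.0-fold (log2 −5.28 ± 0.10), NATA1 38.8-fold (log2 −5.28 ± 0.15), MIOX2 35.0-fold (log2 −5.13 ± 0.07) and PEPC1 32.7-fold (log2 −5.03 ± 0.06). Normexp moved PAP14 from log2 −7.48 to −4.62, PAP85 from −6.44 to −3.21 and MIOX4 from −5.99 to −2.90, without ending their calls.

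At 48 h in wild type 12 of the 27 lists were called, and none with an estimated correlation, whose adjusted p follows the preset one for each list here. All 18 CBF regulon genes (18 adjusted over the list alone, median 2.67, adjusted p = 8.16e-08, 0.21) and all 14 ribosome biogenesis genes were higher (14 adjusted over the list alone, median 1.06, adjusted p = 1.49e-05, 0.21), the latter including the nucleolar proteins FIB2 (2.60), NOP56 (2.04), NOP58 (1.84) and APUM24 (1.68). The 5 DREB1 members were higher (median 3.87, adjusted p = 0.02, 0.285), but under normexp the list was not called (median 2.48, adjusted p = 0.124), and CBF4, at least 2.48-fold higher, was at log2 −0.02. Clock genes were 13 higher and 3 lower (13 and 3 adjusted over the list alone, median 0.89, adjusted p = 0.0154, 0.285). RVE1 (2.94), CCA1 (2.85), ELF4 (2.42) and BOA (2.16) rose most. Flavonoid genes were 14 higher and 4 lower (14 and 4 adjusted over the list alone, median 1.13, adjusted p = 0.0154, 0.21). FLS1 (2.51) and CHI (2.34) rose and DFR (−2.16) fell. Solute and starch genes were 14 higher and 4 lower (14 and 4 adjusted over the list alone, median 0.81, adjusted p = 0.0154, 0.332). GOLS2 (4.56) and BAM3 (3.99) rose and DIN10 (−4.44) fell. Abscisic acid genes were 12 higher and 4 lower (12 and 4 adjusted over the list alone, median 0.58, adjusted p = 0.03, 0.427, 0.0553 under normexp). CYP707A1 (2.30), ABI5 (2.22), HAI2 (1.95, 0.97 under normexp) and NCED3 (1.81) rose.

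The lists that fell at 48 h in wild type were those of jasmonate, heat shock, auxin and senescence genes and of vasculature markers. Jasmonate genes were 3 higher and 16 lower (3 and 17 adjusted over the list alone, median −1, adjusted p = 6.79e-04, 0.21 with an estimated correlation). Among them were PDF1.2A (−4.19), ORA59 (−3.03), VSP2 (−2.95) and VSP1 (−2.77). Heat shock genes were 2 higher and 11 lower (2 and 11 adjusted over the list alone, median −1.08, adjusted p = 0.0182, 0.21 with an estimated correlation). Among them were HSP23.5 (−2.60), ROF2 (−2.24), HSP17.4 (at least 2.17-fold) and HSP90.1 (−2.97, probes −2.97 to 1.36, mean of its probes −0.81). Auxin response genes were 1 higher and 10 lower (1 and 10 adjusted over the list alone, median −0.58, adjusted p = 0.02, 0.21 with an estimated correlation). Among them were IAA6 (−2.68), IAA29 (−1.42), GH3.6 (−1.31) and GH3.5 (−1.23). Senescence genes were 1 higher and 5 lower (1 and 5 adjusted over the list alone, median −0.82, adjusted p = 0.0329, 0.21 with an estimated correlation, 0.0606 with slide as a block). Among them were DIN6 (−3.72), SAG13 (−2.64) and SWEET15 (−1.68). Vasculature markers were 1 higher and 7 lower (1 and 7 adjusted over the list alone, median −0.66, adjusted p = 0.03, 0.427 with an estimated correlation). XCP1 (−1.06), IRX5 (−0.95), XCP2 (−0.77) and IRX3 (−0.66) fell.

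Early transcription factors (10 higher, 4 lower, median 0.43, adjusted p = 0.167) and salicylate genes (6 higher, 10 lower, median −0.11, adjusted p = 0.554) were not called at 48 h in wild type. HSFC1 (2.36), CZF1 (1.24) and ZAT6 (1.17) were higher and WRKY40 (−1.21) lower; among salicylate genes PR2 (−3.50), PR1 (−3.06) and DMR6 (−1.93) were lower and CBP60G (1.97) higher. Root markers divided into 8 higher and 6 lower (median 0.24, adjusted p = 0.691), the iron uptake genes IRT1 (4.41) and FRO2 (3.58) up and the aquaporin genes TIP2;2 (−3.92) and TIP2;3 (−3.64) down. The flowering genes CO (2.52, 1.41 under normexp) and FT (at least 1.62-fold lower) and the replication genes PCNA1 (1.04) and MCM5 (1.04) also changed.

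The direct comparison of 48 h with 3 h in wild type asks how the response shifts with time. CBF3 fell 26.9-fold (log2 −4.75, n = 2), CBF2 16.2-fold (log2 −4.02) and CBF1 11.7-fold (log2 −3.54 ± 0.05), while COR15A rose a further 8.34-fold (log2 3.06), RD29A 5.76-fold (log2 2.53) and KIN1 2.92-fold (log2 1.55); COR47 did not pass (log2 0.36, adjusted p = 0.167). It did pass with slide as a block (0.36, adjusted p = 0.023), quantile scaling (0.50, 0.00297), the mean of its probes (0.85, 1.13e-04) and without wild type 3 h replicate 1 (0.63, 0.0356). XTH20 (18.7-fold, log2 4.22) and COR413IM1 (18.0-fold, log2 4.17) rose, with ARI12 (at least 24.1-fold), BCAT7 (at least 17.8-fold) and SRO4 (at least 3.67-fold). SQE6 (44.5-fold, log2 −5.48), PHI-1 (38.9-fold, log2 −5.28) and SQP1 (38.4-fold, log2 −5.26) fell, with TPS03 (at least 42.7-fold) and PAP14 (at least 38.4-fold). Between the times 15829 genes passed, 8538 higher and 7291 lower at 48 h, and 13 lists were called, 3 of them with an estimated correlation. Those 3 fell: early transcription factors (14 of 15 lower, median −1.70, adjusted p = 2.91e-07, 0.0237 with an estimated correlation), flavonoid genes (19 of 20, median −1.18, 1.06e-08, 0.0237) and jasmonate genes (21 of 22, median −1.81, 8.5e-09, 0.0237). ERF6 (−3.49), ZAT10 (−2.72), DFR (−4.25), LDOX (−4.07), JAZ7 (−4.92) and LOX3 (−3.05) were among them. RNA polymerase II subunit genes were 11 higher and 1 lower (median 0.37, adjusted p = 0.0222, 0.301 with an estimated correlation). Calls of clock genes (median −0.59, adjusted p = 0.0392, 0.314 with an estimated correlation) and vasculature markers (median −0.71, 0.0305, 0.389) ended with slide as a block (0.0585 and 0.0584), and that of heat shock genes (median −1.13, 0.0234, 0.195) under normexp (0.0547).

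In the overexpression plants the CBF genes led the rises at 3 h and GOLS3 those at 48 h. At 3 h CBF3 rose 300-fold (log2 8.23, n = 2), CBF1 263-fold (log2 8.04) and CBF2 160-fold (log2 7.32), with COR15A (2.72), RD29A (3.5), KIN1 (1.15) and COR47 (0.84, adjusted p = 0.0561 without overexpression 3 h replicate 1). RRTF1 and DDF1 rose at least 20.4-fold and 11-fold; XTH25 18.4-fold (log2 −4.20), SEN1 15.5-fold (log2 −3.95), THA1 13.2-fold (log2 −3.72), BCAT-2 (log2 −4.05) and MIOX4 (at least 25.1-fold) fell. At 48 h GOLS3 rose 253-fold (log2 7.98), COR27 60.7-fold (log2 5.92) and ARI12 at least 29.6-fold, with RD29A (5.86), COR15A (5.68), CBF1 (5.0, 32.0-fold), CBF3 (3.80), CBF2 (3.65), KIN1 (2.67) and COR47 (1.21). RTFL21 fell 52.0-fold (log2 −5.70), and THA1, NATA1, MIOX4 and PAP85 fell at least 57.3-fold, 24.0-fold, 20.8-fold and 14.6-fold. At 3 h 14560 genes passed, 6850 higher and 7710 lower, and at 48 h 16542, 8469 higher and 8073 lower. The CBF regulon was 16 higher and 2 lower at 3 h (median 1.3, adjusted p = 1.57e-05, 0.338 with an estimated correlation) and 18 higher at 48 h (median 2.82, 1.52e-07, 0.183). Across the 2 time points 10 and 13 lists were called, 2 and 0 with an estimated correlation.

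Across all 20806 genes the cold responses of the genotypes correlated at r = 0.91 at 3 h (slope 0.916) and r = 0.937 at 48 h (slope 0.941); genes are not independent replicates. Responses built from replicate 1 arrays alone and replicate 2 arrays alone gave 0.89 and 0.856 at 3 h and 0.913 and 0.906 at 48 h. Changes by time of day that the genotypes share enter these correlations too. Of 12067 genes passing in both genotypes at 3 h, 11900 moved the same way and 167 opposite ways; at 48 h these were 15047 and 95 of 15142. Without the background filter, over 25337 genes, r was 0.773 and 0.845, and with 19673 genes above background in all arrays it was 0.941 and 0.964.

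**Figure D2:**
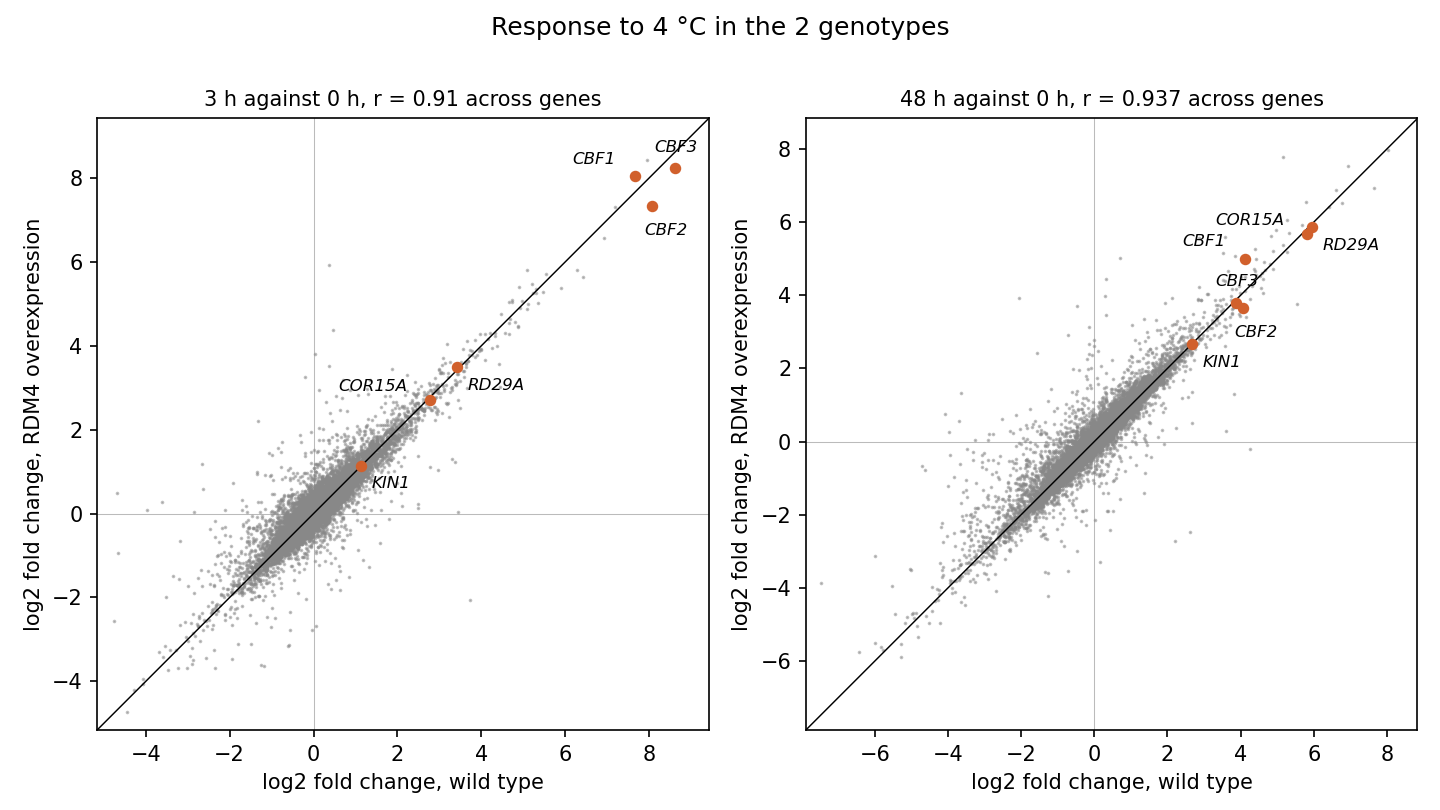
Log2 fold change in the cold in wild type (horizontal) and in 35S::RDM4 plants (vertical) for every tested gene at 3 h and 48 h, n = 2 per group, with the line of equality. Most genes lie along the line (r = 0.91 and 0.937), CBF genes at the upper right at 3 h.

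Before cold, the comparison of genotypes asks what the transgene changes in unstressed seedlings, and the main feature was lower expression of salicylate and defence genes. Of 21 measured, 16 were lower and 5 did not pass (19 lower adjusted over the list alone, median −0.57, adjusted p = 2.3e-16, and adjusted p = 0.0058 with an estimated correlation). The WRKY regulators WRKY38 (log2 −1.37 ± 0.10, n = 2) and WRKY54 (−1.35 ± 0.04, adjusted p = 8.4e-06), the marker PR1 (−1.08 ± 0.13) and the camalexin gene CYP71A13 (−1.02 ± 0.06) were lowest. With slide as a block PR1 (−1.01, adjusted p = 0.206), WRKY38 and CYP71A13 no longer passed, while WRKY54 did. Glucanase gene BG3 was 3.45-fold lower (log2 −1.79 ± 0.10, adjusted p = 4.88e-05) and PCC1 3.36-fold lower (log2 −1.75 ± 0.12, adjusted p = 1.34e-04). In total 2683 genes passed (12.9 %), 994 higher and 1689 lower, of which 20 and 78 reached 2-fold; 37.0 % were higher, against 49.7 % with median scaling. The slide as a block, which leaves 2 residual degrees of freedom, left 79 genes passing, and normexp 1244.

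MRD1 was 22.9-fold lower at 0 h (log2 −4.52 ± 0.55, adjusted p = 0.00193), passing under every setting except the fit of the compared arrays alone, and the seed storage gene CRU3 4.40-fold lower (log2 −2.14 ± 0.10, adjusted p = 2.07e-05), not passing with slide as a block. CLE18 was at least 9.27-fold, GOA at least 3.41-fold, NAC071 at least 3.18-fold, the aquaporin gene TIP1;3 at least 2.87-fold, SWEET10 at least 2.54-fold and GASA3 at least 1.18-fold lower. On the higher side were SRO4 2.99-fold (log2 1.58 ± 0.35, adjusted p = 0.0251), UBQ12 2.49-fold (log2 1.32 ± 0.30, adjusted p = 0.026), FTM1 2.28-fold (log2 1.19 ± 0.04, adjusted p = 9.12e-06) and the methyltransferase gene CMT1 2.17-fold (log2 1.11 ± 0.28, adjusted p = 0.038). NUDT24 was at least 2.73-fold, PLS at least 2.34-fold, NIP2;1 at least 2.17-fold, DEG4 at least 1.63-fold and VIN3 at least 1.11-fold higher. Under normexp VIN3 (−0.34), CMT1 (−0.31), PLS (−0.22), DEG4 (−0.20) and NIP2;1 (−0.13) turned to lower, and NUDT24, SRO4, UBQ12, GOA, GASA3 and SWEET10 no longer passed. FTM1, NAC071, BG3, PCC1 and WRKY54 passed under every setting that tested them. NAC071, dim in the overexpression plants at 0 h, was not tested with probes above background on all arrays. Normexp moved NAC071 from −2.78 to −1.22 and CLE18 from −5.23 to −2.68.

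Of the fixed cold genes only CBF1 passed between genotypes at 0 h. It was 1.17-fold lower (log2 −0.22 ± 0.05, adjusted p = 0.0222), not passing under normexp (−0.55, adjusted p = 0.316), quantile scaling (adjusted p = 0.134), slide as a block (−0.30, adjusted p = 0.276) or without wild type 0 h replicate 2 or overexpression 0 h replicate 1. The CBF1 signal before scaling was only 32 to 69 on the arrays at 0 h. CBF2 (0.75 ± 0.31, adjusted p = 0.152, 1.36 and adjusted p = 4.26e-04 without overexpression 0 h replicate 1), CBF3 (0.14, 0.546), COR15A (0.09, 0.512), COR47 (−0.12, 0.762), RD29A (0.06, 0.785) and KIN1 (−0.15, 0.53) did not pass. Of 18 CBF regulon genes 1 was higher and 17 did not pass (0 adjusted over the list alone, median −0.03, camera adjusted p = 0.992). The median was 0.16 with slide as a block and −0.06 and 0.01 within scan days. The DREB1 family had 1 lower and 4 not passing (median 0.14, camera adjusted p = 0.932). Within scan days its median was 0.25 and −0.01.

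Further groups moved modestly at 0 h. Of 15 early cold transcription factors 8 were lower (9 adjusted over the list alone, median −0.26, adjusted p = 3.52e-04, and adjusted p = 0.0622 with an estimated correlation). Among them were ZAT10 (−0.45), ZAT12 (−0.35), WRKY40 (−0.33) and ZAT6 (−0.33). Of 15 auxin response genes 9 were higher (9 higher and 1 lower adjusted over the list alone, median 0.22, adjusted p = 1.57e-04, and adjusted p = 0.0775 with an estimated correlation). Among them were IAA14 (0.49), SAUR-AC1 (0.45, −0.07 with slide as a block), IAA5 (0.38) and IAA6 (0.37). Of 14 root markers 8 were lower (8 adjusted over the list alone, median −0.24, adjusted p = 6.76e-04, and adjusted p = 0.331 with an estimated correlation, 0.0675 with slide as a block). Among them were RHD6 (−0.41), CASP2 (−0.35) and COBL9 (−0.35), beside vasculature markers of which 0 of 8 passed (median 0.03, camera adjusted p = 0.894). Of 17 cell cycle genes 3 were lower (3 adjusted over the list alone, median −0.08, adjusted p = 0.0434, and adjusted p = 0.196 with an estimated correlation). That call was lost with quantile (0.06) or median scaling (0.0682), slide as a block (0.366) or without wild type 0 h replicate 2 (0.236) and other arrays. None of 27 RNA-directed DNA methylation genes passed (median −0.06, camera adjusted p = 0.527), nor did any of 14 RNA polymerase II subunit genes (median 0.07, camera adjusted p = 0.259). None of the early factors, auxin genes and root markers named passed with slide as a block. Fry, which tests whether a list as a whole departs from 0 using residual rotation, called 9 lists at 0 h.

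Genotype and slide overlap nearly completely, so values within batches are set beside the pooled ones at 0 h. At 0 h and 3 h each scan day held 1 array per genotype, on different slides. Values within scan days are thus single replicate pairs behind the pooled value and cannot separate slide from genotype. With scan day as a block 2967 genes passed. The salicylate median was −0.57 with scan day and −0.52 with slide as a block, and −0.58 and −0.51 within the 2 scan days. Early factors gave −0.26, −0.14, −0.17 and −0.23, auxin genes 0.22, 0.14, 0.22 and 0.23, and root markers −0.24, −0.13, −0.24 and −0.19 in the same order. The count fell to 1194 without wild type replicate 1 at 0 h, 1305 without overexpression replicate 1 and 1288 without overexpression replicate 2.

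**Figure D3:**
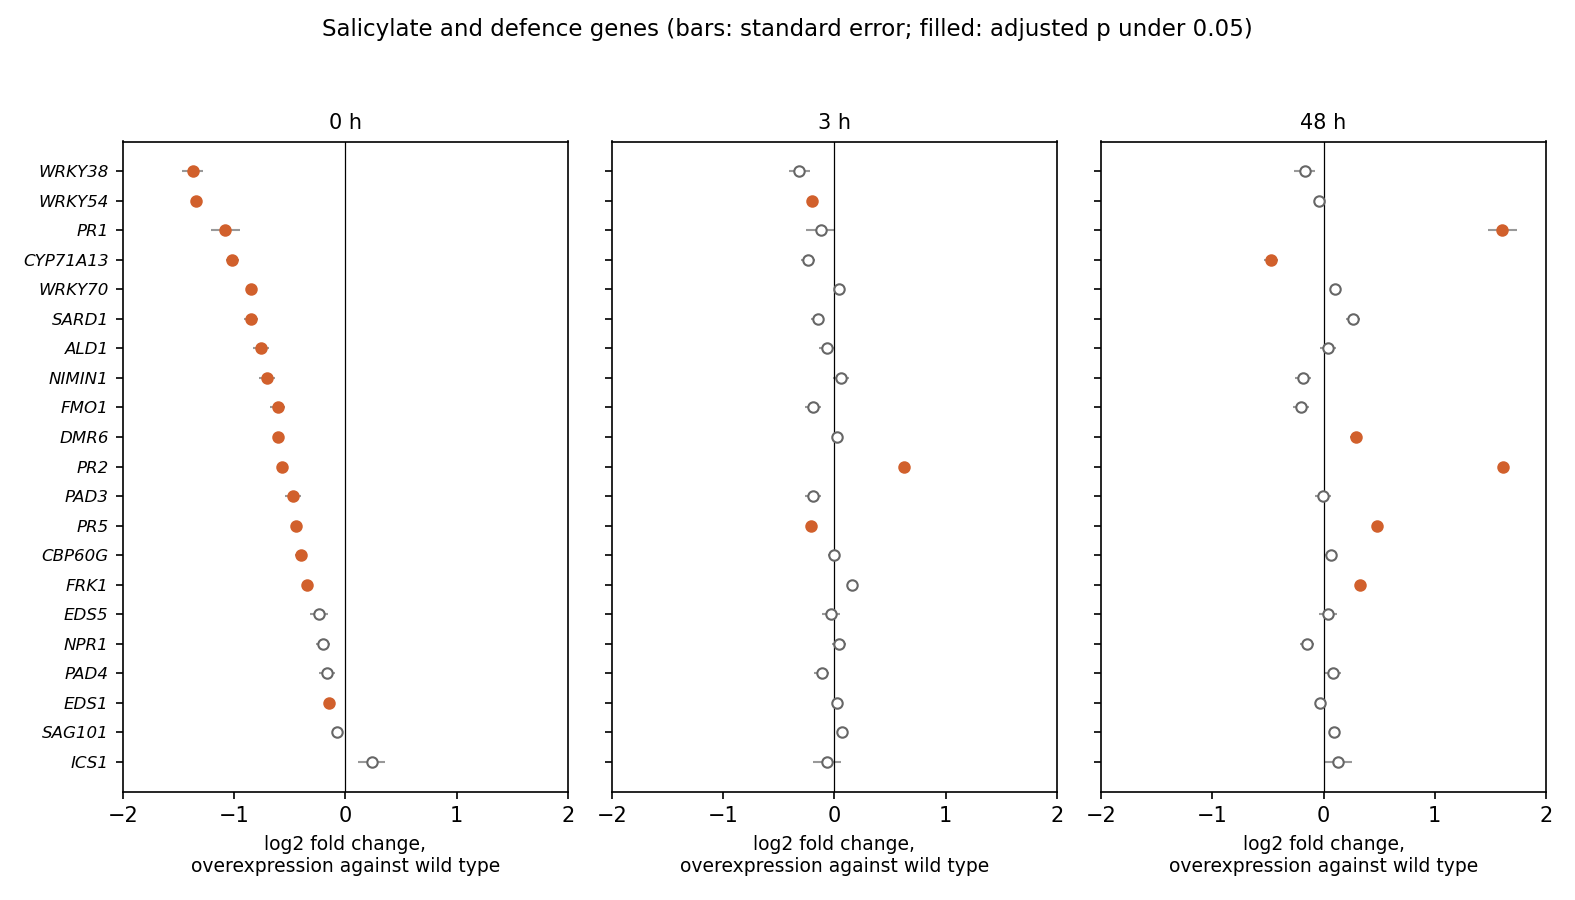
Overexpression minus wild type (horizontal, log2) for 21 salicylate and defence genes at 0, 3 and 48 h of cold; bars are standard errors, n = 2 per group, filled points have adjusted p below 0.05. At 0 h the median is −0.57, and by 48 h PR1 and PR2 are higher at 1.61 and 1.62.

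At 3 h of cold the genotype comparison asks whether the early response ends at a different level, and few genes differed by much. DIN11 was 2.2-fold lower (log2 −1.13 ± 0.05, n = 2, adjusted p = 1.17e-04) and passed under every setting. The starch regulator gene QQS was 1.98-fold lower (log2 −0.98 ± 0.07, adjusted p = 0.00206), lost only with the compared arrays alone and with the 2-fold minimum. PCR1, linked to cadmium resistance, was 1.89-fold higher (log2 0.91 ± 0.05, adjusted p = 2.33e-04). CBF1 (0.16, adjusted p = 0.0933), CBF2 (0.00 ± 0.31, 1), CBF3 (−0.25, 0.279, −0.49 and 0.0429 without overexpression replicate 1 at 3 h), COR15A (0.05, 0.778), COR47 (−0.11, 0.794), RD29A (0.13, 0.552) and KIN1 (−0.13, 0.606) did not pass. In all 1028 genes passed (4.94 %), 473 higher and 555 lower, 25 and 5 of them at least 2-fold; 46.0 % were higher, against 36.0 % with median scaling.

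Lower at 3 h were also MRD1 19.1-fold (log2 −4.26 ± 0.55, adjusted p = 0.0129), AACT1 (−1.18 ± 0.22, adjusted p = 0.0339), NATA1 (−0.90, adjusted p = 0.028), the defensin genes PDF1.2b (−0.90 ± 0.10), PDF1.2c (−0.84 ± 0.13), PDF1.3 (−0.83 ± 0.11) and PDF1.2A (−0.67 ± 0.06), and SYP52 (−0.66 ± 0.05, probes −0.66 to −0.04). MRD1 did not pass without either wild type array at 3 h or without overexpression replicate 2. Higher were the cytochrome P450 gene CYP71B9 2.37-fold (log2 1.24 ± 0.14, adjusted p = 0.00993), DGK6 2.11-fold (log2 1.08 ± 0.13, adjusted p = 0.0114), ANN6 1.91-fold (log2 0.94 ± 0.20, adjusted p = 0.0417), CYP71B38 1.76-fold (log2 0.81 ± 0.19, adjusted p = 0.0493), EC1.2 at least 2.80-fold, CYP71B25 at least 1.82-fold and PUP19 at least 1.76-fold. GRP16 (1.17) was not well above background in either genotype. Most of these calls are fragile: 17 genes passed under normexp, 28 with slide as a block, 15 with the compared arrays alone and 118 without overexpression replicate 2 at 3 h, but 2041 with array weights and 1263 with scan day as a block.

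Of the lists, 4 were called at 3 h between genotypes, 0 with an estimated correlation, and fry called 3. Flavonoid genes were 3 lower and 17 not passing (5 adjusted over the list alone, median −0.10, adjusted p = 0.00141, and adjusted p = 0.249 with an estimated correlation, 0.125 with slide as a block). Among them were GSTF12 (−0.38, probes −0.38 to −0.17), LDOX (−0.26) and DFR (−0.22). Abscisic acid genes were 2 higher and 1 lower (7 and 1 adjusted over the list alone, median 0.11, adjusted p = 0.0132, and adjusted p = 0.502 with an estimated correlation, 0.112 with slide as a block), with ABI2 (0.28) and HAB1 (0.21) up and EM6 (−0.48) down. Clock genes had 1 higher, BOA (0.27), and 19 not passing (3 adjusted over the list alone, median 0.09, adjusted p = 0.0197, and adjusted p = 0.502 with an estimated correlation). Cell cycle genes had 2 lower, CYCB1;2 (−0.22) and TSO2 (−0.20), and 15 not passing (4 adjusted over the list alone, median −0.07, adjusted p = 0.0197, and adjusted p = 0.249 with an estimated correlation). The clock, abscisic acid and cell cycle calls each ended without wild type replicate 2 at 3 h (adjusted p 0.0583, 0.0565 and 0.0565). CBF regulon genes had 1 lower, GOLS3 (−0.29), and 17 not passing (1 adjusted over the list alone, median −0.06, camera adjusted p = 0.452, 0.15 with slide as a block, −0.07 and −0.04 within scan days). Salicylate genes were 1 higher and 2 lower (median −0.07, camera adjusted p = 0.485), with PR2 (0.62) higher and PR5 (−0.21) and WRKY54 (−0.20) lower. Of 14 root markers 3 were higher, FRO2 (0.75), IRT1 (0.60) and TIP2;3 (0.36), and 11 did not pass (4 higher and 1 lower adjusted over the list alone, median 0.04, camera adjusted p = 0.106, −0.02 within scan day 2). None of the list members named at 3 h passed with slide as a block.

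At 48 h the genotype comparison asks whether acclimated plants differ. The pathogenesis-related genes PR2 (log2 1.62 ± 0.05, n = 2, adjusted p = 2.48e-06) and PR1 (1.61 ± 0.13, adjusted p = 4.37e-04), the defensin gene PDF1.2A (1.52 ± 0.06, adjusted p = 1.19e-05), PCR1 4.95-fold (log2 2.31 ± 0.05, adjusted p = 2.09e-07) and the receptor-like kinase gene CRK6 3.24-fold (log2 1.70 ± 0.05, adjusted p = 2.16e-06) were higher in the overexpression plants. CBF1 was 1.59-fold higher (log2 0.67 ± 0.05, adjusted p = 2.46e-04, 0.65 with scan day as a block, and 0.64 with adjusted p = 0.0454 with slide as a block). Normexp ended the CBF1 call (0.62, adjusted p = 0.592) and that of PR1 (0.97, adjusted p = 0.0618). CBF2 (0.35, adjusted p = 0.631, 0.0498 without overexpression 0 h replicate 1), CBF3 (0.06, 0.868), COR15A (−0.05, 0.82), COR47 (−0.10, 0.868), RD29A (−0.04, 0.92) and KIN1 (−0.16, 0.642) did not pass. On the arrays at 48 h the processed signal before scaling was 232896 to 243330 for COR47, 163698 to 182315 for RD29A and 328275 to 362010 for KIN1. The arrays' 75th percentiles ranged from 3816 to 5562. Signals that hardly follow the array's scale can hide a difference, although no spot was called saturated, so these genes say little about the genotypes at 48 h. In all 777 genes passed (3.73 %), 540 higher and 237 lower, with 60 and 12 at least 2-fold.

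CRK7 was 3.40-fold higher at 48 h (log2 1.77 ± 0.24, adjusted p = 0.00616), and LBD8 at least 4.54-fold, RLP23 at least 2.13-fold (probes 1.69 to 2.65), CRK37 at least 2.1-fold, the root iron regulator MYB72 at least 2.05-fold, PAP14 at least 1.32-fold and EXL6 at least 1.17-fold; the deposited value table put EXL6 at −0.03. Lower were MRD1 10.1-fold (log2 −3.33 ± 0.55, adjusted p = 0.0146, not passing without any of the 4 arrays compared), DSI-1VOC 2.15-fold (log2 −1.10 ± 0.13, adjusted p = 0.00267, −0.53 in the deposited value table), the seed aquaporin gene TIP3;1 1.89-fold (log2 −0.92 ± 0.05, adjusted p = 3.78e-05), the homeobox gene HB53 1.77-fold (log2 −0.83 ± 0.06, adjusted p = 2.78e-04), LEA18 1.73-fold (log2 −0.79 ± 0.09, adjusted p = 0.00186) and ECP63 (−0.78 ± 0.11, adjusted p = 0.00634). SRO4 was at least 3.42-fold lower. Normexp ended the calls of CRK7, LBD8, RLP23, CRK37, MYB72, PAP14, DSI-1VOC, LEA18, ECP63 and SRO4. PCR1, CRK6, PR2, PDF1.2A, TIP3;1 and HB53 passed under every setting, except that TIP3;1 and HB53 did not reach the 2-fold minimum. Normexp moved CRK6 to 1.05. With normexp 171 genes passed, with slide as a block 257 and with scan day as a block 655.

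Between genotypes 5 lists were called at 48 h, all higher, 0 with an estimated correlation, while fry called 6. Abscisic acid genes were 5 higher and 1 lower (10 and 1 adjusted over the list alone, median 0.22, adjusted p = 1.66e-07, and adjusted p = 0.12 with an estimated correlation), with RD29B (0.97, adjusted p = 0.251 under normexp), HAI1 (0.73) and RD26 (0.39) up and EM6 (−0.49) down. Flavonoid genes were 7 higher (7 and 1 lower adjusted over the list alone, median 0.09, adjusted p = 2.5e-04, and adjusted p = 0.12 with an estimated correlation). UF3GT (0.56), UGT75C1 (0.47), GSTF12 (0.43) and PAP1 (0.39) were highest. Jasmonate genes were 3 higher (7 and 1 lower adjusted over the list alone, median 0.15, adjusted p = 0.00104, and adjusted p = 0.12 with an estimated correlation), with CORI3 (0.41) and AOC2 (0.36). Early factors were 3 higher (4 adjusted over the list alone, median 0.12, adjusted p = 0.00232, and adjusted p = 0.12 with an estimated correlation), namely WRKY40 (0.29), ERF6 (0.22, probes −0.16 to 0.22) and DEAR1 (0.21). Salicylate genes were 5 higher and 1 lower (6 and 1 adjusted over the list alone, median 0.06, mean 0.18, adjusted p = 0.0193, and adjusted p = 0.196 with an estimated correlation), with PR5 (0.48) up and CYP71A13 (−0.47, probes −0.47 to −0.09) down. Normexp ended the calls of EM6, UF3GT, PAP1, CORI3, WRKY40, ERF6, DEAR1 and CYP71A13 at 48 h. The salicylate call ended with scan day (0.0626) or slide (0.213) as a block. Of 18 CBF regulon genes 0 passed (0 adjusted over the list alone, median −0.01, camera adjusted p = 0.814); with slide as a block the median was 0.12 and camera called it (0.00342), as it did without overexpression 48 h replicate 2 (0.08, 0.048). Within scan day 2 and within the shared slide the medians were 0.20 and 0.21 for abscisic acid, 0.10 and 0.11 for flavonoid, 0.12 and 0.12 for jasmonate, 0.11 and 0.10 for early factors and 0.06 and 0.03 for salicylate genes. For the CBF regulon they were 0.02 and 0.12. KIN1, whose signal hardly followed the array's scale at 48 h, is a member of that list.

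**Figure D4:**
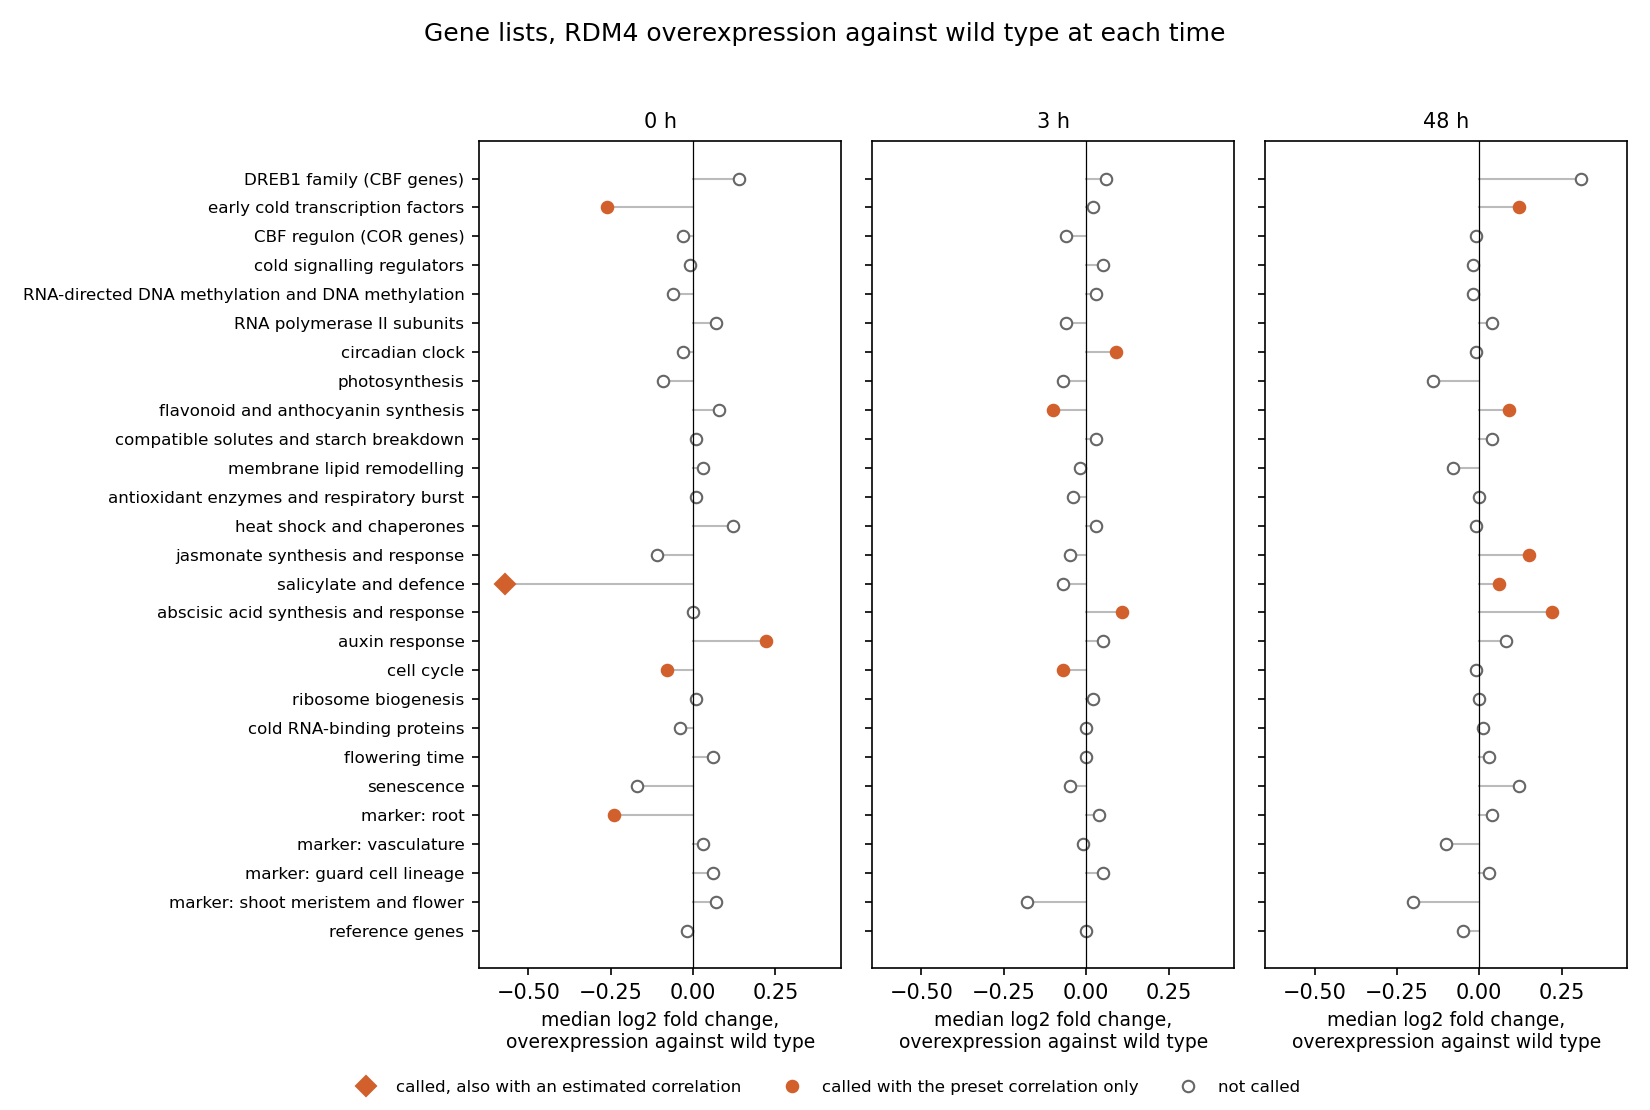
Median overexpression minus wild type difference (horizontal, log2) of 27 gene lists at 0, 3 and 48 h; diamonds are called with preset and estimated correlation, filled circles with the preset only, open circles not called, n = 2 per group. Only the salicylate list at 0 h, at −0.57, is a diamond. The CBF regulon has pooled medians of −0.03, −0.06 and −0.01, but 0.12 at 48 h with slide as a block.

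Averaged over the 3 times, the genotype comparison asks how the genotypes differ when the times are pooled. RDM4 (5.54 ± 0.06, 46.6-fold, n = 2 per group) led the rises and MRD1 was 16.4-fold lower (log2 −4.04 ± 0.31, adjusted p = 3.42e-04). UBQ12 2.02-fold (log2 1.01, 0.49 under normexp), the heat factor gene HSFA6A 1.92-fold (log2 0.94) and ATSAC1B (0.93) were higher, and the oleosin gene OLEO2 1.72-fold (log2 −0.78) lower. NAC071 (−1.25, −0.52 in the deposited value table) and NATA1 (−0.79) were lower too, as fitted log2 differences only, being near background in the overexpression plants at 0 h and at 48 h. Slide as a block ended the calls of UBQ12, HSFA6A, ATSAC1B and NATA1. CBF1 averaged 0.20 ± 0.03 (adjusted p = 0.00441), from −0.22 at 0 h to 0.67 at 48 h. That call ended under normexp (0.06, adjusted p = 0.87), in the deposited value table (0.113), with the scanner median signal (0.136) and with slide as a block (0.284). CBF2 passed only without overexpression 0 h replicate 1 (0.57, adjusted p = 0.00121). Of 18 CBF regulon genes 0 passed (median −0.04, camera adjusted p = 0.753, 0.12 with slide as a block). In all 3176 genes passed (15.3 %), 1388 higher and 1788 lower; 24 passed with slide as a block, 3277 with scan day, and 1813, 1858, 1929 and 1971 without wild type 3 h replicate 1, wild type 48 h replicate 1, overexpression 3 h replicate 2 and overexpression 0 h replicate 1. Of 100 splits of the arrays that keep 2 arrays of each time on each side, the split by genotype gave the most genes, 3176 against 1304 for the highest other. That excludes chance only if arrays are exchangeable, and here genotype nearly coincides with slide, which the splits do not exclude as a source.

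Averaged over time, 4 lists were called, 0 with an estimated correlation. Salicylate genes were 1 higher and 10 lower (1 and 14 adjusted over the list alone, median −0.10, adjusted p = 4.77e-04, and adjusted p = 0.201 with an estimated correlation). WRKY38 (−0.62), CYP71A13 (−0.58) and WRKY54 (−0.53) were lower and PR2 (0.56) higher. Abscisic acid genes were 7 higher and 1 lower (11 and 2 adjusted over the list alone, median 0.10, adjusted p = 4.77e-04, and adjusted p = 0.412 with an estimated correlation). RD29B (0.32) and HAI1 (0.31) were higher and EM6 (−0.66) lower, but RD29B did not pass under normexp (0.17, adjusted p = 0.5), in the deposited value table (0.0817) or with slide as a block (0.126). Auxin genes were 5 higher and 1 lower (median 0.11, adjusted p = 0.00172, and adjusted p = 0.201 with an estimated correlation, 0.226 with slide as a block), with IAA14 (0.36). None of the list members named for the average passed with slide as a block. Cell cycle genes had 2 lower (median −0.05, adjusted p = 0.0307, and adjusted p = 0.201 with an estimated correlation, 0.338 with slide as a block). Within scan day 2 the medians were −0.12 for salicylate, 0.12 for abscisic acid and 0.09 for auxin genes.

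Whether the transgene alters the cold response itself is asked by the difference of responses, overexpression minus wild type, and the salicylate genes again lead. At 3 h 14 of 21 responded more positively and 7 did not pass (18 adjusted over the list alone, median 0.51, adjusted p = 1.22e-13, and adjusted p = 0.00962 with an estimated correlation). PR2 (1.2), WRKY54 (1.15), WRKY38 (1.06) and PR1 (0.96) differed most. The PR1 call at 3 h ended under normexp (0.89, adjusted p = 0.115), in the deposited value table (0.76, 0.132), with the scanner median signal (0.76, 0.117) and with slide as a block (0.96, 0.116). It also ended, at 0.95 to 0.96, without any of the 4 arrays at 0 h or either overexpression array at 3 h. At 48 h 14 did (18 adjusted over the list alone, median 0.55, adjusted p = 1.8e-20, and adjusted p = 0.00309 with an estimated correlation), with PR1 (2.69 ± 0.19, adjusted p = 1.5e-04), PR2 (2.19 ± 0.07, adjusted p = 3.5e-06), WRKY54 (1.31) and WRKY38 (1.21). Early factors gave 9 more positive at 3 h (10 adjusted over the list alone, median 0.35, adjusted p = 2.78e-05, and adjusted p = 0.0337 with an estimated correlation) and 8 at 48 h (9 adjusted over the list alone, median 0.29, adjusted p = 9.29e-07, and adjusted p = 0.0173 with an estimated correlation). Among them were WRKY40 (0.60 and 0.62) and ZAT10 (0.46 and 0.60), which like WRKY38 did not pass with slide as a block at either time. The 2 differences share the 4 arrays at 0 h, so they are not separate observations, and much of each reflects the lower starting level. With slide as a block the salicylate medians were 0.54 and 0.62, and within scan day 2 they were 0.51 and 0.65.

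Among the fixed cold genes only CBF1 passed in the differences of responses, at 0.38 ± 0.07 at 3 h (adjusted p = 0.0195, n = 2) and 0.89 ± 0.07 at 48 h (adjusted p = 2.77e-04). Both calls ended under normexp and with slide as a block although the differences were larger there. They were 0.67 (adjusted p = 0.408) and 1.17 (0.269) under normexp and 0.43 (0.107) and 0.95 (0.0581) with slide as a block. Both differences rest on a CBF1 signal at 0 h of only 32 to 69 before scaling. The 3 h call also ended, at 0.35 to 0.39, with quantile scaling (adjusted p = 0.0845), the deposited value table (0.242), the scanner median signal (0.217) and without wild type 3 h replicate 1 (0.0655) or 2 (0.0615) or overexpression 3 h replicate 2 (0.0697). CBF2 (−0.75, adjusted p = 0.305, and −0.41, 0.687), CBF3 (−0.39, 0.237, and −0.07), COR15A (−0.05 and −0.14), RD29A (0.07 and −0.10), COR47 (0.01 at 3 h) and KIN1 (0.02 at 3 h) did not, and the CBF regulon had 1 higher and 1 lower at 3 h (median −0.01) and 0 at 48 h (median 0.02, camera adjusted p = 0.856). At 48 h RD29A is limited by its signal as in the genotype comparison above. Without overexpression 0 h replicate 1 CBF2 passed at −1.36 (adjusted p = 0.00286) and −1.01 (0.0042), and without overexpression 3 h replicate 1 CBF3 passed at 3 h at −0.62 (0.0328). PCR1 (2.19 ± 0.06, adjusted p = 1.03e-05) and CRU3 (2.02 ± 0.14, adjusted p = 5e-04) were more positive at 3 h and BGLU28 (−0.96 ± 0.14), MLO9 (−0.90 ± 0.19), LTP4 (−0.88 ± 0.08) and DIN11 (−0.88 ± 0.07) more negative. At 48 h FTM1 (−1.12 ± 0.06, adjusted p = 3.1e-05) and BXL1 (−0.72 ± 0.09, adjusted p = 0.00292) were more negative. Genes near background in some groups, given as fitted log2 differences only, were GOA (3.89), EC1.2 (3.77), NAC071 (2.08) and NUDT24 (−1.92) at 3 h, and SRO4 (−5.09), TIP1;3 (4.98), GOA (4.23), LBD8 (4.12), RLP23 (3.86), PAP14 (3.6), NUDT24 (−1.80) and MLO9 (−1.17) at 48 h. Normexp turned NUDT24 (0.06 and 0.02) and MLO9 (0.16 and 0.03) to the other sign and ended the calls of GOA, EC1.2, NAC071, SRO4, TIP1;3 and LBD8. CRU3, BGLU28, LTP4 and BXL1 did not pass with slide as a block.

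At 3 h 1531 genes passed in the difference of responses, 992 more positive and 539 more negative, and at 48 h 1133, 940 and 193. The more positive share was 64.8 % at 3 h, against 42.9 % with median scaling, and 83.0 % at 48 h, against 71.3 %. Normexp left 340 and 397, slide as a block 94 and 257, and scan day as a block 1549 and 1037; at 3 h the count was 574 without wild type 3 h replicate 2, and at 48 h 664 without wild type 48 h replicate 2. Other called lists were root markers (9 more positive at 3 h, median 0.30, adjusted p = 3.66e-06, and adjusted p = 0.154 with an estimated correlation). At 48 h there were 4 of these (median 0.28, adjusted p = 4.46e-07, and adjusted p = 0.126 with an estimated correlation), and FRO2 (0.77 at 3 h, 0.80 at 48 h) and IRT1 (0.54 and 0.58) were more positive at both times. Abscisic acid genes followed (2 at 3 h, median 0.13, adjusted p = 0.00945, and adjusted p = 0.463 with an estimated correlation), with 4 at 48 h (median 0.21, adjusted p = 1.35e-06, and adjusted p = 0.126 with an estimated correlation), with RD29B (1.29, and 1.35 with adjusted p = 0.097 under normexp) and HAI1 (0.73) at 48 h. Auxin genes were more negative (3 at 3 h, median −0.15, adjusted p = 0.00826, and adjusted p = 0.175 with an estimated correlation, 1 at 48 h, median −0.16, adjusted p = 0.00327, and adjusted p = 0.126 with an estimated correlation). Flavonoid genes were called more negative at 3 h (7, median −0.25, adjusted p = 9.17e-05, and adjusted p = 0.117 with an estimated correlation), with GSTF12 (−0.53) and UGT75C1 (−0.37). Jasmonate genes were called more positive at 48 h (5, median 0.15, adjusted p = 0.00327, and adjusted p = 0.126 with an estimated correlation, 0.0867 under normexp), with PDF1.2A (1.87) and LOX4 (0.78). Slide as a block ended the calls of FRO2, IRT1, GSTF12, UGT75C1, HAI1 and LOX4.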

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

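The tests of the salicylate pattern were written after its result was seen, and those of the seed storage genes, the value table column and the splits before their outcome was known. Results are given here because the cold response differed between genotypes, or because a deposited column differed from its scanner file.

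The difference of the cold responses passed for 1531 genes at 3 h and 1133 at 48 h (n = 2 per group). Of the fixed cold genes CBF1 differed, by 0.38 at 3 h and 0.89 at 48 h. The differences were larger but no longer passed under normexp, at 0.67 (adjusted p = 0.408) and 1.17 (0.269), and with slide as a block, at 0.43 (0.107) and 0.95 (0.0581). At 3 h the named genes were GOA (3.89), EC1.2 (3.77), PCR1 (2.19), NAC071 (2.08), CRU3 (2.02), NUDT24 (−1.92), BGLU28 (−0.96), MLO9 (−0.90), LTP4 (−0.88) and DIN11 (−0.88). At 48 h they were SRO4 (−5.09), TIP1;3 (4.98), GOA (4.23), LBD8 (4.12), RLP23 (3.86), PAP14 (3.6), NUDT24 (−1.80), MLO9 (−1.17), FTM1 (−1.12) and BXL1 (−0.72). List medians were 0.51 at 3 h and 0.55 at 48 h for salicylate genes, 0.35 and 0.29 for early cold factors, 0.30 and 0.28 for root markers, 0.13 and 0.21 for abscisic acid genes and −0.15 and −0.16 for auxin genes. Flavonoid genes gave −0.25 at 3 h and jasmonate genes 0.15 at 48 h. Of these lists only the salicylate genes and early factors stayed called with an estimated correlation; the others had adjusted p from 0.117 to 0.463. Of the genotype effects called at both 0 h and 48 h (377 genes), 163 were lower and then higher against 43.8 expected, 81 higher at both times against 25.8 and 126 lower at both against 19.2. The expected counts take the comparisons as independent, whereas the wild type arrays of all times lie on the same slides, so the excess in the same direction is not evidence of a genotype effect. Averaged over times, 1 of 100 splits of the arrays gave as many genes as the real 3176, the genotype split itself, against 1304 for the highest other. That excludes chance only for exchangeable arrays and does not exclude slide, since 24 genes passed with slide as a block.

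The lower salicylate genes at 0 h could come from the slides, since genotype and slide overlap, and the difference of 3 h responses inside the slides of replicate 1 (median 0.53) does not test the level at 0 h. With slide as a block the median at 0 h was −0.52 and the list stayed called, in a fit with 2 residual degrees of freedom. That fit ties the genotypes together only through overexpression 48 h replicate 1. Overexpression 0 h replicate 2, alone on its slide, adds nothing to it. The fit therefore counts only weakly against an additive slide effect as the only cause. Background correction or scaling did not remove the pattern either, the median nearest 0 being −0.52, and without any of the 4 arrays at 0 h it was again at least as low as −0.52. These medians argue against the signal processing and a single array at 0 h as the only cause. A slide effect stays open, mainly one that is not additive. So does whether the transgene lowers these genes or the seedlings of the genotypes differed in growth state or plate when sampled. Root markers had a median of −0.24 at 0 h, called at the preset correlation but not with an estimated one (adjusted p = 0.331) or with slide as a block (−0.13, 0.0675). Whether the samples differed in their share of root tissue was not tested.

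In a list of seed storage genes made after values were seen and not tested as a set, 9 of 14 were lower in the overexpression plants at 0 h and 5 did not pass, with a mean of −0.92 over the 11 above background. If samples held unequal amounts of seed material of the same composition, and these genes were silent elsewhere, they would differ by a common factor. The SD of their log2 fold changes over the mean standard error was 5.1. Seedling expression of their own would also break a common factor, so this ratio cannot decide. The largest replicate difference in mean level was 0.12, but this says nothing about seed material varying from plate to plate if replicates shared a plate, and whether they did is not stated. An unequal share of seed material, plate variation, developmental age and genotype all stay open.

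In the deposited value table the column of overexpression 48 h replicate 2 is not the median signal of its scanner file, which it equals for 1.45 % of spots, and RDM4 there is 250960 against 275395. A second scan of the same array could account for that: the log2 ratio of the column to the scanner value had a median of −0.09 and an SD of 0.21. Deviations of repeated spots correlated with the array's own scanner file at r = 0.32 and with another array at up to 0.52, but scanner files of different arrays correlated at up to 0.71, so this r cannot identify an array. Whether the column is a rescan stays open. Results other than those under the value table setting do not use it.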

How the results depend on the processing

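The scanner median signal, slide as a random block and the list tests under normexp, the value table, scan day, slide and single array omission were chosen after results were seen. RDM4 between genotypes kept its direction and passed under every setting, and the cold counts moved by less than 1.5 times under every setting except a 2-fold minimum. Of the lists followed across settings, which are mainly those already called so that gained calls are hardly counted, 1774 results stayed as they were and 116 were weaker; of the named gene calls 26201 stayed, 106 were stronger, 2334 weaker and 24 reversed.

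Counts at least 2-fold, in the order wild type 3 h, 48 h, 48 h against 3 h, overexpression 3 h and 48 h, were 1959, 3826, 3156, 1988 and 3853, and for genotypes at 0, 3 and 48 h, their average and the differences of responses 98, 30, 72, 31, 62 and 148. In that last order normexp gave 1244, 17, 171, 955, 340 and 397, the deposited values 1425, 52, 314, 1400, 472 and 445, the scanner median signal 1660, 176, 334, 1783, 631 and 522, and slide as a block, under which the CBF regulon was called at 48 h with a median of 0.12, 79, 28, 257, 24, 94 and 257. Of these, normexp shared 1092, 17, 168, 903, 308 and 351 genes with the counts of the report, the deposited values 1300, 51, 294, 1312, 434 and 416, and slide as a block 35, 7, 188, 9, 50 and 159. Scan day as a block gave 2967, 1263, 655, 3277, 1549 and 1037, replicate as a block 3130, 1429, 895, 3873, 1683 and 1180, and slide as a random block (correlation 0.151) 2643, 1040, 915, 2496, 1989 and 1287. The compared arrays alone gave 998, 15 and 156 at 0, 3 and 48 h and 648 for the 48 h difference; slide and compared arrays leave 2 residual degrees of freedom, which lowers power by construction. Without the filter 280 genes passed at 3 h between genotypes and 875 in the 3 h difference, trended robust variances gave 1715 and array weights (0.578 to 1.35) 2041 at 3 h. With replicate as a block COR47 passed for wild type 48 h against 3 h (0.36, adjusted p = 0.016). It ended the cell cycle call at 0 h (adjusted p = 0.0543). Replicate differences correlated between groups at −0.05 to 0.29, 5 of 15 above 0.1, including all 3 wild type pairs (0.17, 0.19 and 0.29), whose arrays share slides. The response correlation was 0.773 and 0.845 without the filter, 0.941 and 0.964 with probes bright on all arrays, 0.937 and 0.962 in the value table and 0.937 and 0.961 with the scanner median signal, and 0.943 at 48 h under normexp. Slide as a block left fewer genes than normexp at 0 h, averaged and in both differences. Genes near background lost calls or turned direction under normexp and the value table, so signal over background limits what is known of them; the cause was not tested.

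The lowest and highest counts when each array was left out were 12540 to 14408 for wild type at 3 h, 15291 to 16571 at 48 h, 14545 to 16001 for 48 h against 3 h, 13049 to 14821 and 15453 to 16539 for overexpression at 3 and 48 h. Between genotypes they were 1194 to 3137 at 0 h, 118 to 1143 at 3 h, 423 to 948 at 48 h, 1813 to 3883 averaged, and 574 to 1703 and 664 to 1265 for the differences. RDM4 stayed at 5.36 to 5.56, 5.63 to 5.77 and 5.33 to 5.59, r at 0.827 to 0.904 and 0.887 to 0.933, list calls at 83 to 94 (12 with camera at an estimated correlation), and the CBF regulon median at −0.04 to 0, −0.12 to 0.03 and −0.08 to 0.08. The lone array left in a group is assumed to vary like the other groups. In the order wild type 0 h replicates 1 and 2, 3 h replicates 1 and 2, 48 h replicates 1 and 2, overexpression 0 h replicates 1 and 2 and 3 h replicate 2, the 3 h count was 509, 425, 170, 161, 262, 262, 471, 465 and 118. The 3 h difference, in the same order without wild type 0 h replicate 2, was 651, 587, 574, 976, 969, 955, 620 and 582. The 0 h count was 1194, 1305 and 1288 without wild type replicate 1 and overexpression replicates 1 and 2, the 48 h count 423 and 498 without wild type 48 h replicates 1 and 2, and the average 1813, 1858, 1971 and 1929 without wild type 3 h and 48 h replicate 1, overexpression 0 h replicate 1 and 3 h replicate 2. The 48 h difference was 753, 671, 664 and 726 without wild type 0 h replicate 1, wild type 48 h replicates 1 and 2 and overexpression 0 h replicate 1.

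Reversed under normexp were, at 0 h between genotypes, VIN3 (−0.34), CMT1 (−0.31), PLS (−0.22), DEG4 (−0.20) and NIP2;1 (−0.13); in the differences of responses MLO9 (0.16 and 0.03) and NUDT24 (0.06 and 0.02); in cold FUL (−0.01, overexpression 48 h), VIN3 (−0.23, wild type 3 h), CBF4 (−0.02) and MYB11 (−0.21) in wild type at 48 h. Quantile scaling reversed RDM4 in the 48 h difference (0.29), the value table NUDT24 (0.31) and EXL6 (−0.03), the scanner median signal FUL (−0.02), and slide as a block SAUR-AC1 (−0.07) and NYE1 (−0.05). The mean of probes reversed HSP90.1 (−0.29 at 48 h, −0.02 averaged), ERF6 (0), MYB60 (0) and TUB2 (−0.02). The cause was not tested.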

Other observations

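Genes of the low oxygen response, which serve fermentation and hypoxia signalling, were higher in the overexpression plants before cold, a group outside the planned lists. Of 14 genes 10 were higher and 0 lower at 0 h (n = 2), with FTM1 (log2 1.19 ± 0.04), WIP4 (0.62), the alcohol dehydrogenase gene ADH1 (0.53), PCO2 (0.51), the pyruvate decarboxylase gene PDC1 (0.49), LBD41 (0.45) and HB1 (0.35). In wild type cold the list split: at 3 h 2 rose and 9 fell (median −0.69), with HRA1 (−1.71), FTM1 (−1.21), WIP4 (−1.15) and LBD41 (−1.06) lower and PDC1 (1.59) higher. At 48 h 4 rose and 8 fell (median −0.51, mean 0.06), ADH1 rising 17.3-fold (log2 4.11) and PDC1 15.6-fold (log2 3.96). Between genotypes 1 gene was higher and 2 lower at 3 h and 3 were higher at 48 h, and the response was more negative for 10 genes at 3 h and 5 at 48 h.

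A list of seed storage and late embryogenesis genes, made after values were seen, was counted and not tested as a set. In wild type 9 of 14 measured rose and 2 fell at 3 h (median 0.62), and 2 rose and 10 fell at 48 h (median −1.72), with PAP85 (−6.44) and CRU3 (−3.33). In the overexpression plants 12 rose and 1 fell at 3 h (median 1.49) and 2 rose and 10 fell at 48 h (median −1.11). Between genotypes at 0 h 9 were lower and 5 did not pass (median −1.01), with CRU3 (−2.14), CRA1 (−1.21), ECP63 (−1.12), OLEO2 (−1.11), EM6 (−1.01) and PER1 (−0.98). At 3 h 2 were lower, and at 48 h 2 were higher and 4 lower, CRU3 at 0.68 and TIP3;1 at −0.92.

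The low oxygen list was written after FTM1 and WIP4 were seen among the changed genes, so its test left them out. Whether the low oxygen response as a whole differs between genotypes at 0 h was tested by camera on the other 12 members. The median was 0.32 and the unadjusted p was 8.87e-09, and with an estimated correlation it was 0.00432. Because the list was drawn up after values in these data were seen, these p-values are not independent support for a shared shift. No value with slide as a block was taken for this list, and genotype nearly coincides with slide. A slide effect, higher submergence or crowding on plates could produce the difference as well as the transgene, and no measurement here separates them.

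Genotype effects at 0 h and at 3 h were both called for 305 genes, of which 101 were higher at both against 22.6 expected, 130 lower at both against 45.1 and 47 lower and then higher against 38.4. For 3 h and 48 h 169 genes were called at both, 83 higher at both against 12.3, 53 lower at both against 6.32 and 27 lower and then higher against 14.4. The expected counts take the comparisons as independent, whereas arrays of different times share slides and wild type replicate differences correlated at 0.17 to 0.29 between times. An excess in the same direction is therefore not evidence of a genotype effect. Across genes the effects correlated at r = 0.183 between 0 h and 3 h, 0.282 between 3 h and 48 h and 0.087 between 0 h and 48 h; genes are not independent replicates.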
